A study of Drosophila melanogaster with 3 samples.

How the data were processed

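Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in Drosophila melanogaster carrying a GFP-tagged form of Deformed (Dfd), a homeodomain transcription factor of the Hox family, with an antibody against GFP. The labels list 3 samples, 1 ChIP sample and 2 input samples (chromatin set aside before the immunoprecipitation). The title of the ChIP sample covers replicates 1 and 2 together, so the 1 peak list stands for both and has no replicate error. Input peak lists or coverage were not analysed here. The stage is given only as the code 10T-W3L, which the labels do not spell out. The growth protocol in the labels describes flies in cages and the collection of embryos, so the material is named here by its code. Per the labels' protocols, chromatin was cross-linked with 1.8% formaldehyde, sonicated and immunoprecipitated, and the recovered DNA went directly into library preparation.

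Peaks were called with MACS, per the file headers. Reads were aligned with Bowtie to the BDGP5 genome build, per the submitters' processing notes. The versions of both tools, how the replicates were combined, which control was used in calling and which limit was set are not given in the sources used here. The deposited score of each peak is the authors' own value from MACS. Early versions of MACS write -10 log10 of the p-value in that column, and the smallest deposited score, 50, is the value that scale gives at a p of 1e-05. No header states the scale, so the score was used only within this list, to rank and filter peaks and to compare median scores between sets of its peaks. The other deposited columns, other than the peak name, are the authors' start and end positions, given here counted from 1. The number of reads behind each library is not given in the sources used here, so the depth is unknown and no interval that needs it was computed. The intervals below, except the bootstrap interval over windows, treat each peak as 1 count and cover counting error only.

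The design fixed before the data were examined included tests of transcription start sites, annotation classes, gene lists and sequence motifs, all of which need the genome and annotation of the build of the peaks. The gene table at hand belongs to Release 6 of the genome, whereas the sequence names and processing notes place the peaks on BDGP5 (Release 5). Coordinates were not converted between builds, so those tests were not run. Under the naming rule fixed before the data were examined, the 25 highest scoring peaks are named, by position only, and no peak is assigned to a gene. The 23 fixed gene lists and 18 fixed motifs therefore have no result here.

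From the deposited positions, the peaks were counted on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. Because arm lengths of the build were not used here, the length of an arm was taken as the span from its first to its last peak. A span cannot exceed its arm, so densities are if anything too high, by an unknown share that can differ between arms. Counts per arm were compared with the span shares by a chi-square test, and the density of X or 4 with that of the 4 large autosomal arms by an exact conditional test of 2 Poisson rates, two-sided, with Clopper-Pearson limits at 95%. A chi-square test was set before the data were examined, but against arm lengths from an assembly of the build, in whose place spans were used. The separate tests of X and of 4 against the autosomal arms were chosen after the counts per arm were seen. Peaks lie in groups, which makes such limits too narrow, so the X density was also tested on complete 1 Mb windows by 100000 permutations of windows and given a 95% interval from 10000 bootstrap draws of windows. Spacing was tested against 1000 random placements of the peaks, without overlap, at their own widths between the first and the last peak of their arm. The two-sided p of that test cannot fall below 0.002. Assembly gaps were not excluded from the placements. Score and width were compared by Spearman's rho with 10000 permutations, and medians by 10000 permutations. Peaks are not independent replicates, so these p-values describe this list. Families of tests were adjusted by the Benjamini-Hochberg method.

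The alternatives were higher score limits, other neighbour distances, the inclusion of heterochromatic sequences, and, chosen after the data were seen, the joining of peaks under 1 kb apart, placement within each peak's own 1 Mb window and leaving out each arm in turn. The spacing test was tried on simulated lists of 3054 peaks. Of 20 uniform lists, 2 were called clustered or dispersed at 0.05, with 100 placements per list. All 20 lists in which 1 in 5 peaks had been moved beside another were called clustered. The density ratio was tried on independent Poisson counts per arm. For an X made 1.5 times as dense, the mean recovered ratio was 1.504 and 19 of 20 intervals held the true ratio. Those counts held no grouping, so this does not show that the intervals hold for grouped peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.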

Results

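The data are the peaks called after precipitation of GFP-tagged Deformed with chromatin, in fly material of the stage coded 10T-W3L. A peak is a call, and no test here shows that it is a binding site. Deformed is a Hox protein of the Antennapedia complex that specifies head segments, and the GFP tag allowed it to be precipitated with an antibody against GFP. The study's design names chromatin input as the control. The list held 3159 peaks on 14 sequences of BDGP5, of which 3054 lay on the 6 chromosome arms and 105 on other sequences. The peaks had a median width of 687 bp (quartiles 605 and 808 bp, range 256 to 4109 bp). On the arms they covered 2278 kb, or 1.92% of the spans between the first and last peak. The list combined both replicates, so the values have no replicate error, and no comparison with input was made.

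Peaks were found on all 6 arms, and were most closely packed on the small chromosome 4 and on X. X carried 773 peaks over a span of 22.3 Mb, or 34.7 per Mb. The 4 large autosomal arms together carried 2219 peaks over 95.1 Mb, or 23.3 per Mb. The X density was thus 1.49 times the autosomal density (95% exact interval 1.37 to 1.62, p = 4.0e-20). Chromosome 4 carried 62 peaks over 1.21 Mb, or 51.2 per Mb, which was 2.19 times the autosomal density (interval 1.68 to 2.82, exact p = 7.5e-08). Both intervals count grouped peaks as independent and are therefore too narrow.

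Among the large autosomal arms, 2L had the fewest peaks for its span, with 479 peaks or 21.0 per Mb. The densities of the others were close to each other, at 24.4 per Mb on 2R (516 peaks), 24.6 per Mb on 3L (572 peaks) and 23.4 per Mb on 3R (652 peaks). Over these 4 arms alone the counts departed from the span shares at p = 0.0465 (chi-square 7.98), in a test that counts grouped peaks as independent. Over all 6 arms the chi-square was 129 on 5 degrees of freedom (p = 4.1e-26). X held 25.3% of the arm peaks (95% exact interval 23.8 to 26.9) against 18.8% of the summed span.

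The difference between X and the autosomal arms was also seen in windows. The 22 complete 1 Mb windows of X held 35.0 ± 10.5 peaks (mean ± SD over windows), and the 93 windows of 2L, 2R, 3L and 3R held 23.4 ± 7.38. The difference of 11.6 peaks per window had a permutation p of 1e-05, the smallest that 100000 permutations can give, and the ratio of the means had a bootstrap interval of 1.29 to 1.71. Both treat windows as independent, and X is a single chromosome, so they describe spread among windows and not among chromosomes. Of the X windows, 19 of 22 lay above the autosomal mean, and the densest, X 12160068 to 13160067, held 57 peaks. The single complete window of chromosome 4, from 62765 to 1062764, held 48 peaks, and the highest of the autosomal windows held 47, so this comparison rests on 1 window (exact one-sided permutation p = 0.0106, the smallest it allows). Among the 10% of arm peaks with the highest scores the X ratio was 1.32 (interval 0.999 to 1.73, exact p = 0.0507), and chromosome 4 had 1 such peak, a ratio of 0.337 (interval 0.00849 to 1.90, exact p = 0.412).

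**Figure D1:**
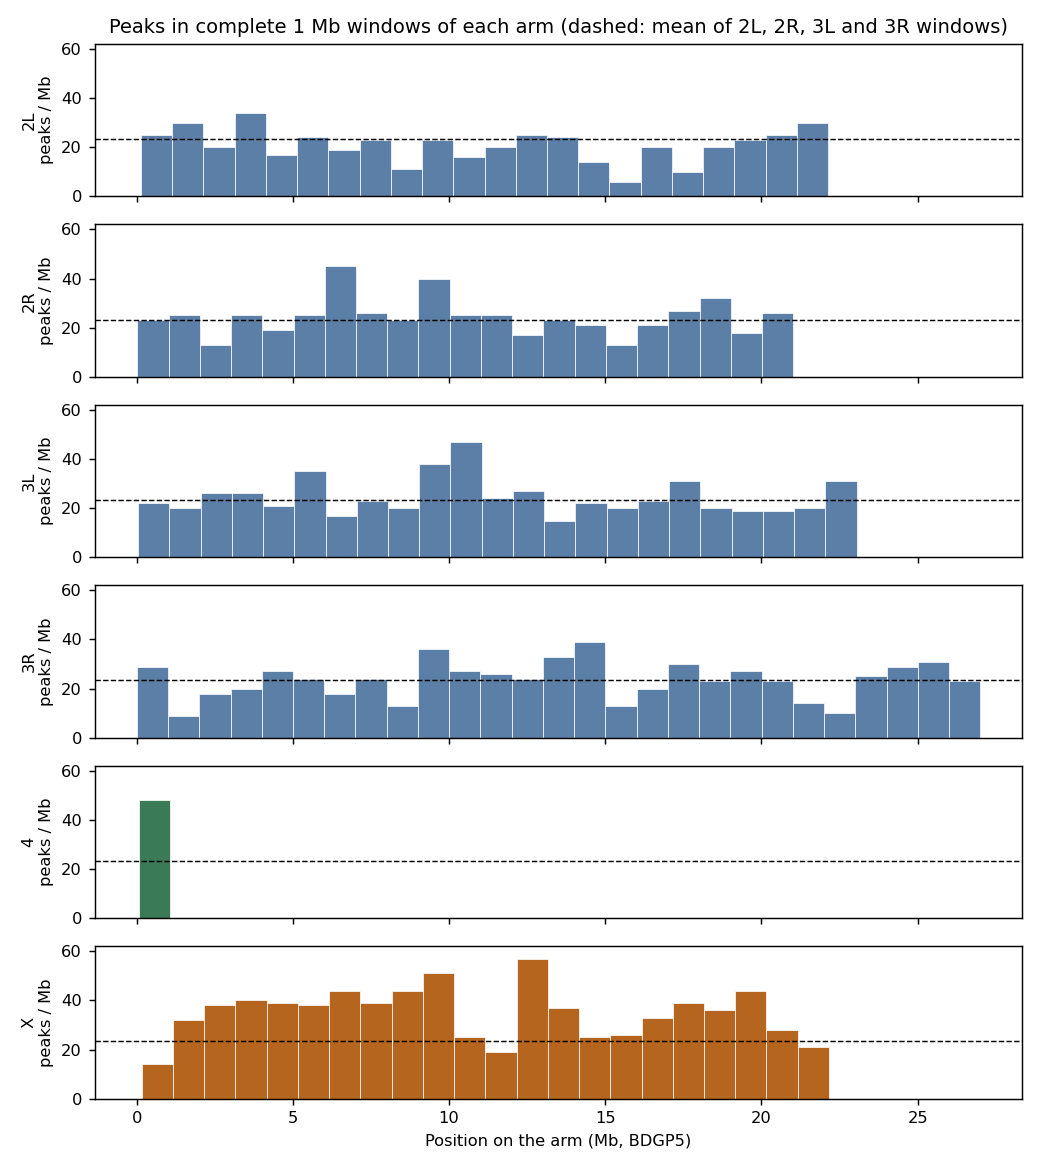
Number of peaks (vertical axis) in each complete 1 Mb window along the 6 arms (horizontal axis, position in Mb on BDGP5), 1 panel per arm, with the mean of the 2L, 2R, 3L and 3R windows as a dashed line. On X, 19 of 22 windows stand above that line, as does the single window of chromosome 4 with 48 peaks.

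The peaks lay in groups along the arms. Of the 3054 arm peaks, 1022 (33.5%) had the centre of another peak within 5 kb, against 20.6% ± 0.965 (mean ± SD of 1000 random placements), a 1.62-fold excess that no placement reached (highest 23.7%, two-sided permutation p by random placement = 0.002, the smallest possible). The median distance to the nearest centre was 9.32 kb, against 13.6 kb ± 0.403 (SD) under random placement. At 2 kb the excess was 2.25-fold, with 14.9% of peaks against 6.63%, and at 20 kb it was 1.10-fold, with 70.7% against 64.2%. Some neighbouring peaks lay close together, since 207 of 3048 gaps between consecutive peaks were under 1 kb and 26 were under 100 bp. Whether the caller had split such peaks from 1 region was not tested. With peaks under 1 kb apart joined, 2847 regions remained, and 23.3% of them had a neighbour within 5 kb against 19.1% at random (highest placement 22.0%). Joined regions were tested only at 5 kb over all arms together. How far splitting adds to the excess at 2 kb or on single arms was therefore not tested.

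The grouping was found on 5 of the 6 arms. On 2L, 34.7% of peaks had a neighbour within 5 kb, 2.10 times the random share. The excess was 1.80-fold on 3L, 1.64-fold on 2R, 1.55-fold on 3R and 1.44-fold on X, each with an adjusted p of 0.0024 over the 6 arms (Benjamini-Hochberg, random placement). The shares were 34.4% against 19.1% at random on 3L, 31.2% against 19.1% on 2R, 28.4% against 18.3% on 3R and 38.0% against 26.4% on X. The random share is higher on denser arms, so the folds do not rank the arms by grouping. On chromosome 4 the share was 30.6% against 36.3% ± 7.53 (SD) at random, which did not pass (adjusted permutation p = 0.527). With 62 peaks, grouping on chromosome 4 could be tested only coarsely.

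**Figure D2:**
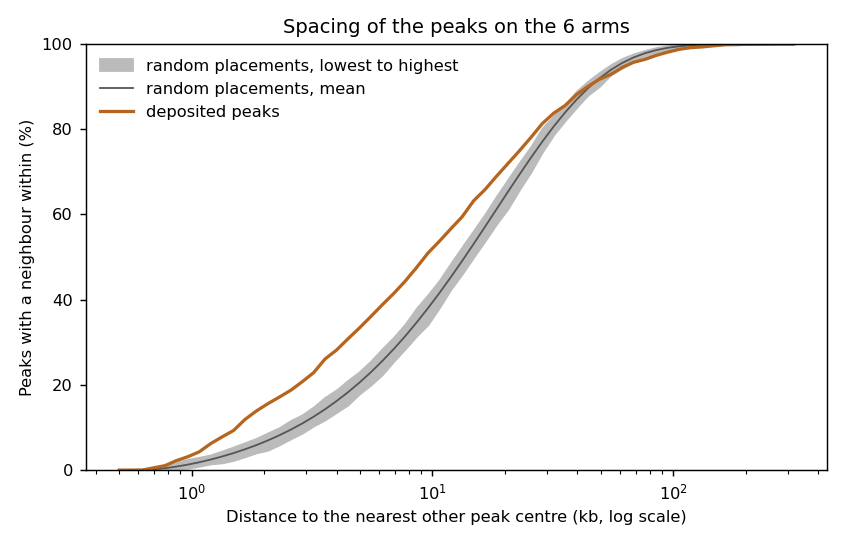
Share of the 3054 arm peaks (vertical axis, percent) with another peak centre within a given distance (horizontal axis, kb, log scale), for the deposited peaks and for 1000 random placements, shown as their mean and their full range. At 5 kb the deposited peaks reach 33.5% and the highest placement 23.7%.

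The densest 100 kb stretch lay on X, from 12542265 to 12631609, and held 19 peaks with scores of up to 551.52. Random placement on X gave a densest stretch of 10.8 peaks on average and of 16 at most. The densest stretches of the other large arms were on 3R from 14228219 to 14323229 (14 peaks), on 2R from 20159915 to 20232297 (13 peaks), on 3L from 10674816 to 10772857 (13 peaks) and on 2L from 7836814 to 7929434 (12 peaks). The densest stretch of each of these 5 arms exceeded the mean of random placement (adjusted p from 0.002 to 0.00719, Benjamini-Hochberg over the 6 arms, one-sided). The highest placement nevertheless reached 12 peaks on 2L and 14 on 2R. With placement within each peak's own 1 Mb window, the adjusted one-sided p ran from 0.006 to 0.0312. The highest such placement held 13 peaks on 2L and 15 on each of 2R, 3L and 3R. On chromosome 4 the densest stretch held 11 peaks against 10.5 at random (adjusted permutation p = 0.437). These stretches were picked after their counts were seen, as the largest of each arm, and the random values are likewise the largest of each placement. The longest peakless stretch within an arm was 571 kb on 2L, from 16809266 to 17380620. Its ends lay 572 kb apart between peak centres, against 352 kb ± 56.5 (SD) for the longest such distance in random placements (one-sided permutation p by random placement = 0.00799).

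Most peaks were only moderately above the lowest score in the list. Scores ran from 50 to 2801.74 with a median of 81.6, and 2056 peaks (65.1%, exact 95% interval 63.4 to 66.7) scored under 100. Only 72 peaks scored above 500. Higher scoring peaks were wider, with Spearman's rho of 0.72 across the 3054 arm peaks (permutation p = 1e-04, the smallest possible, peaks not being independent replicates). Score and width come from the same peak calling, so the test does not show a relation apart from the calling. The 306 peaks in the highest 10% of scores had a median width of 955 bp, against 675 bp for the other 2748. The median score was 80.3 on X and 81.8 on the large autosomal arms, a difference of -1.50 that was not larger than permutation of the peaks gave (p = 0.402).

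Of the 25 highest scoring peaks, 16 lay on the arms and 9 on Uextra, a set of scaffolds not placed on any chromosome. The highest was on X from 8188165 to 8190204, 2040 bp wide with a score of 2801.74. It lay in a stretch from 8096830 to 8193392 that held 12 peaks with a median score of 59.9. The second was on 3L from 5533189 to 5534590, with a score of 1968.08. Further peaks on 3L were at 9143940 to 9145279 (score 1614.46) and at 20815990 to 20816948 (score 1343.55). On 3R the highest were at 367898 to 369043 (score 1568.12) and at 26343661 to 26344711 (score 1223.59). The highest on 2R was at 15046979 to 15048829 (score 1272.59) and the highest on 2L at 778882 to 779853 (score 1249.65). The remaining 8 arm peaks of the 25 scored from 923.52 to 1132.2. By arm, 3L and 3R gave 5 peaks each, and 2L, 2R and X gave 2 each. The arm peaks among the 25 were 959 to 2344 bp wide, whereas the 9 on Uextra were 331 to 770 bp wide. The 3 highest on Uextra scored 1946.14, 1928.02 and 1807.99, and the other 6 from 916.2 to 1452.31.

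Peaks on the unplaced scaffolds were narrower and scored higher than arm peaks. The 68 peaks on U and Uextra, the unplaced scaffolds of the assembly, had a median score of 213 and a median width of 428 bp, against 81.0 and 691 bp on the arms (differences of 132 in score and -262 bp in width, each permutation p = 1e-04, the smallest possible). Of them 35 (51.5%, exact 95% interval 39.0 to 63.8) reached the score of the highest 10% of arm peaks. The 32 peaks on the heterochromatic scaffolds had a median score of 78.7 and a median width of 684 bp, and 0 of 32 reached that score (exact upper limit 10.9%). The mitochondrial genome carried 5 peaks with a median score of 115 and a highest score of 299.06, at 4464 to 4879.

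**Figure D3:**
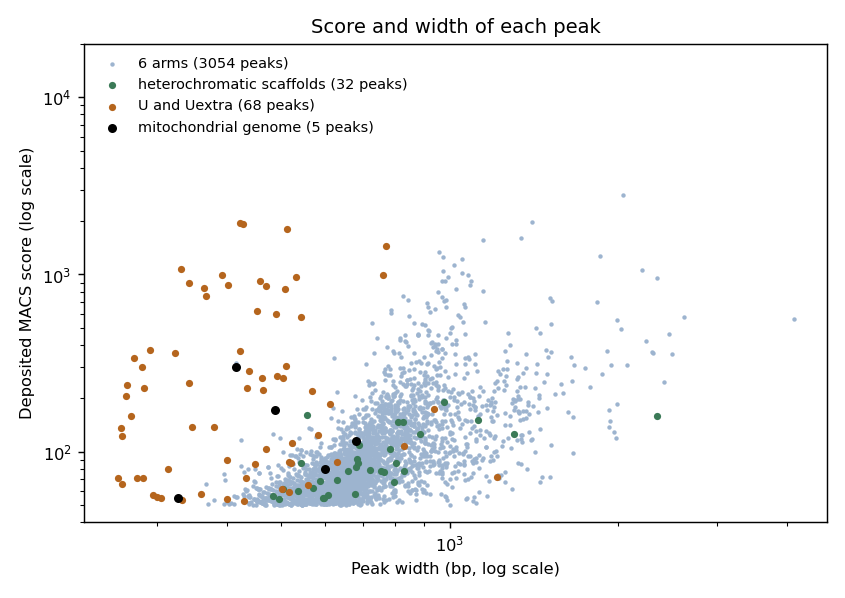
Deposited MACS score (vertical axis, log scale) against peak width (horizontal axis, bp, log scale), 1 point per peak, coloured by the kind of sequence. Arm peaks rise in score with width (rho 0.72), whereas the 68 peaks on U and Uextra include narrow peaks with scores of up to 1946.14.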

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

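Tests of dense X stretches, of the X depth difference and of copy number were chosen after the result was seen. The upper 50% of scores was set beforehand as an alternative, and was read as a test of weak calls only after its counts were seen. The joining of peaks and the placement within 1 Mb windows were added once the list had been seen, before their own outcome was known.

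Peaks were called on sequences outside the 6 arms, which the comparison of arm densities does not use except in the alternative that adds the heterochromatic scaffolds. There were 51 peaks on the Uextra scaffolds, 17 on the U scaffolds, 32 on the heterochromatic scaffolds and 5 on the mitochondrial genome. They are given here because they lie outside the main measurement, and their number does not show whether they are binding or background. The peaks on U and Uextra were narrower and scored higher than those on the arms. Among peaks under 500 bp wide, their median score was 172.8 above that of the arm peaks (228 against 54.8, permutation p = 1e-04, the smallest possible). That value restates the pattern, since score rises with width on the arms. Reads of many copies stacked on 1 scaffold copy and binding of the tagged protein to repeated sequence cannot be told apart, because both would give it and the input was not analysed here. No relation of score and width was detected in these 68 peaks (rho 0.15, permutation p = 0.227). The 5 mitochondrial peaks scored from 54.7 to 299.06.

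The second pattern is the higher density of peaks on X. Splitting of regions by the caller into peaks under 1 kb apart does not account for it. The ratio was 1.475 (interval 1.35 to 1.61) after such peaks were joined. Neither do a few dense stretches, since without the 5 densest windows of X the ratio of window means was still 1.332 (permutation p = 1.7e-04), nor weak calls alone, since it was 1.405 (interval 1.25 to 1.58) in the upper 50% of scores. A difference in read depth between X and the autosomes that the control did not remove could not be told apart from a difference in binding. The median score on X was -1.5 from that of the autosomal arms (permutation p = 0.402), which decides nothing, because a list that ends at a fixed score can gain peaks without a shift of its median. No biological explanation was tested.

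The third pattern is the grouping of peaks. After peaks under 1 kb apart were joined, 23.32% of regions still had a neighbour within 5 kb, above the highest placement at 22.0%. Splitting into peaks under 1 kb apart is therefore not the whole cause. Joined regions cannot lie under 1 kb apart whereas placed ones can, so the size of the remaining excess is not a measure of how much splitting adds. With each peak placed at random within its own 1 Mb window, the observed 33.46% stood above the highest placement at 25.1%, which argues against regional density on the Mb scale as the whole cause. No biological explanation was tested.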

How the results depend on the processing

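Joining of peaks, placement within 1 Mb windows, windows of X and leaving out arms were chosen after seeing the data. All 14 sequences for score against width were chosen then too, as was the test of X density against the autosomal arms. So were the tests of chromosome 4 density and of the densest stretches, with their alternatives. Of 30 alternatives over the arm densities, grouping, score against width and densest stretches, 27 kept the direction and the side of the 0.05 threshold. The exceptions all used the 10% of peaks with the highest scores, where 306 peaks remain. There the X ratio was 1.32 (exact p = 0.0507), the share with a neighbour within 5 kb was 4.58% against 1.99% at random (permutation p = 0.0719), and the chromosome 4 ratio reversed to 0.337, which rests on 1 peak. The fewer peaks limit these tests, and the cause of the chromosome 4 reversal was not tested. The X ratio ranged from 1.32 to 1.57, the latter with heterochromatic sequences included. That alternative added only 3 peaks over 0.083 Mb to X (XHet). To the autosomal arms it added 14 peaks over 3.24 Mb (2RHet), 10 over 1.82 Mb (3LHet), 4 over 1.33 Mb (3RHet) and 1 peak (2LHet). The higher ratio thus reflects sparse autosomal scaffolds and shows nothing more about X. Leaving out each arm in turn gave a grouping excess of 1.55-fold to 1.70-fold. The alternatives set beforehand for start sites, annotation classes, gene lists, motifs and score by position class were not run, since they need a genome of the peaks' build. The depth of the libraries is unknown, and what it limits could not be examined. No paired analysis was possible because the ChIP replicates share 1 peak list and the inputs were not analysed here.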

Other observations

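Chromosome 4 had the highest density of peaks of the 6 arms. Of its 62 peaks, 28 (45.2%) lay in the upper 50% of arm scores, against 50.8% on the large autosomal arms (Fisher's exact test, p = 0.44), and 1 (1.61%) lay in the highest 10% of arm scores, against 233 of 2219 (10.5%) on the large autosomal arms, an odds ratio of 0.140. For the highest 10%, Fisher's exact test gave p = 0.0176, and 0.0704 after Benjamini-Hochberg adjustment over the 4 tests of X and 4 in the upper 50% and upper 10% of scores, so the difference did not pass. The highest score on chromosome 4 was 205.28, whereas each of the other 5 arms reached at least 1249.65. Those arms carried 479 to 773 peaks each, and a highest score tends to rise with the number of peaks. Whether the lower value on chromosome 4 goes beyond its fewer peaks was not tested. The density ratio of 4 to the autosomal arms was also taken by score class, with exact intervals. It was 1.84 in the lowest 25% of scores (13 peaks, 0.973 to 3.17). It was 3.08 in the next 25% (21 peaks, 1.89 to 4.75) and 2.68 in the 25% after that (19 peaks, 1.60 to 4.23). From the 75th to the 90th percentile it was 1.85 (8 peaks, 0.793 to 3.69). In the highest 10% it was 0.337 (1 peak, 0.00849 to 1.90). The intervals held 1 in the lowest 25%, from the 75th to the 90th percentile and in the highest 10%. Whether the ratio differs between these classes was not tested. The X ratio in the same classes was 1.50, 1.65, 1.45, 1.40 and 1.32, and the share of X peaks in the upper 10% (9.31%) was not shown to differ from the autosomal share (Fisher's exact test, adjusted p = 0.44).

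No relation was detected between the scores of neighbouring peaks. Over 578 adjacent pairs within 5 kb the scores had a Spearman's rho of 0.04 (permutation of scores within arms, p = 0.353). Peaks with a neighbour within 5 kb had a median score of 81.7, and isolated peaks one of 80.7 (difference 1.04, permutation p = 0.524). A stretch of 2R from 9887896 to 9951090 held 11 peaks with a median score of 149 and a highest score of 959.64. The longest run of nearly adjoining peaks was on 3R from 11239270 to 11243968, with 4 peaks. A run of 7 peaks lay within 13.7 kb of the U scaffolds, from 5288385 to 5302117, with scores from 71.32 to 300.31. On 2RHet, 1 peak was deposited with a start before the first base of the sequence.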
